A study of Homo sapiens with 8 samples.

How the data were processed

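The data were 8 two-colour microarrays of SK-N-SH cells, 2 for each of 4, 8, 16 and 24 h of 20 µM PGJ2. Per the labels, cDNA of treated cells was marked with Cy5 and cDNA of vehicle cells of the same time with Cy3, through a dendrimer labelling kit, and both were hybridised to a spotted oligonucleotide array of human genes. Per the labels, the arrays were scanned on a GenePix 4000B scanner with the lasers set so that the brightest spot lay just under saturation, and read with GenePix Pro, whose version is not given in the sources used here. No dyes were exchanged. Groups and replicate numbers came from the sample titles.

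The deposited scanner files hold, per spot, the foreground and local background intensity of each channel as scanned, with no normalization, per the file headers. They also hold the percent of saturated pixels per spot in each channel, per the file headers. The deposited series matrix holds log2 ratios. Set against the scanner values they followed the log2 ratio of background-subtracted spot medians, treated over vehicle (r of at least 0.99997 on each array), and each column's median was 0. Their centring and direction were thereby settled. A correlation does not show the slope, so it did not test their log2 scale. They cover 5586 to 15735 spots per array, only spots without a flag but not all of those, and the rule behind that further filter is not known. The matrix was used as an alternative only.

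Each array has 19200 spots, with 288 empty positions and 51 spots whose ID is unknown, and 18665 different probe IDs. Names came from the array's own IDs and descriptions and from a RefSeq gene table of assembly GRCh38.p14, used for names only. By RefSeq accession 8324 probes were named, by a current symbol in the description 322 and by an older symbol 431, so that 9077 probes named 8954 genes and 9588 stayed unnamed. Of 5161 probes named by accession whose description also gave a symbol, 5109 (99.0%) gave the same gene by both. The files give no genome build, so no coordinates are printed. A gene with several probes (96 genes) was represented by its brightest probe.

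Background was corrected with normexp (offset 50) on the spot means, and arrays were normalized by global loess within each array, with empty and unidentified spots at weight 0, in limma 3.58.1 under R 4.3.3. Spots with a negative flag were left out; these were spots not found, from 548 to 5546 per array, and empty positions, and no spot carried the flag for bad spots. Up to 243 spots per array that lay outside the scanned image, with no signal in either channel, were left out as well. Spots of the same probe were averaged, including 197 spots of a GAPDH probe. A probe was kept when its foreground mean was above the background median plus 2 background standard deviations in at least 1 channel on both arrays of at least 1 time. Saturated spots were kept, and a spot counted as saturated from 50% saturated pixels. Where a probe was saturated on all arrays, or not well above background on any, in 1 channel, a fold is given as a bound from the per-channel values after loess and Aquantile normalization, which is open to dye bias.

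Per array, 28.3% to 83.8% of the probes were above background in Cy5, and up to 91.5% in Cy3. The mean log2 ratio of the GAPDH spots lay between -0.11 and 0.35 on the 8 arrays. Their standard deviation was 0.52 on 24 h replicate 2 and between 0.11 and 0.25 on the other 7. An array was counted as having signal at empty positions when over 20% of these were above background in Cy5.

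The model had 1 coefficient per time, fitted with lmFit over all 8 arrays. This leaves 4 residual degrees of freedom for a probe measured on all arrays (9539 of 16413) and fewer for the others. The eBayes step added 5.32 prior degrees of freedom. The tests were each time against 0, the mean of the 4 times against 0, the mean of 16 and 24 h minus the mean of 4 and 8 h, and a moderated F test of any difference between times. P-values were adjusted by Benjamini-Hochberg and called under 0.05. Of 33 gene lists fixed before the data were examined, 32 had at least 5 measured genes. They were tested with camera in its form for ranked statistics, because it takes probes with missing arrays, with a preset correlation of 0.01, two-sided, and again with a correlation estimated on the probes measured on all arrays (9539), beside fry on the same probes. Blood cell and Schwann cell lists had too few such genes for the estimate. With an estimated correlation camera also uses the 4 residual degrees of freedom, in place of a number near that of the genes.

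The fit was tested on simulated data with the real missing spots and spreads and 200 changed probes per run. The changed probes were drawn from those measured on all arrays, with independent normal noise. Recovery for probes with missing arrays was therefore not tested. Over 15891 probes for the average over times, 99.5% of 2-fold and 100% of 4-fold changes were recovered. Over 16076 probes at 24 h, 16.5% and 99.0% were recovered, and over 15891 probes for late minus early, 3.0% and 97.0%. Unchanged probes were also called. With 2-fold and 4-fold changes they numbered 16 and 18 for the average, 5 and 17 at 24 h, and 0 and 14 for late minus early.

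Genes named in the text followed a rule fixed before the data were examined. It took the 12 largest called increases and decreases averaged over times, among probes with a gene name measured on at least 7 arrays with the same sign on all. It took the 5 largest called in each direction at each time with the same sign on both arrays, and the 6 largest late minus early in each direction, of which there were none. It took the 4 members with the smallest p of each called list and 2 of every other list. It also took 24 genes whatever their values, of which 4 were not measured in the fit. The text names fewer than the rule gives, and names outside it are said to be chosen after their values were seen.

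Alternatives fixed beforehand were normexp with offset 10, no background correction, spot medians, print-tip loess, median centring, scaling between arrays, no filter and a filter on all 8 arrays. Further ones were keeping spots not found, the replicate number as a block, eBayes with trend and robust, array weights, each time fitted alone, a minimum 2-fold change, the series matrix, each array left out in turn, an estimated correlation, and the mean over a gene's probes. Chosen after seeing the data were leaving out the 2 dimmest arrays, a filter against the 95th percentile of the empty positions, and a term for arrays with signal at empty positions. Gene names and figures used Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9, and limma used statmod 1.5.0. Scan dates and slide numbers are not given in the files, so that batches could not be tested. Only 16 h replicate 1 and 24 h replicate 1 had no spot outside the scanned image, against 120 to 243 on each other array. Their r across probes (0.56) was also the highest of any pair, and whether they form a batch was not tested.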

Results

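The series measured how prostaglandin J2 (PGJ2), a cyclopentenone prostaglandin, changed the transcripts of human SK-N-SH cells, an established neuroblastoma line. Cultures received 20 µM PGJ2 or its DMSO vehicle for 4, 8, 16 or 24 h, and only cells still attached at harvest were used. RNA from treated cells (Cy5) and from vehicle cells of the same time (Cy3) was hybridised to the same array, with 2 arrays per time and 8 in all. Every value below is a log2 ratio of treated over vehicle cells. The Cy5 channel carried the treated cells on every array, so a dye effect specific to a probe is part of each ratio against 0, while it cancels in a difference between times. Nothing in the labels says that the arrays came from separate cultures, so the p-values of probes measure the spread between these arrays, which may be technical. The p-values of gene lists by camera with a preset correlation set the genes of a list against other genes. Genes are not independent replicates, so these p-values do not measure the spread between arrays.

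Signal differed between arrays. The share of probes above background in the treated channel ran from 28.3% (8 h replicate 1) to 83.8% (4 h replicate 2), and in the vehicle channel it was also highest on the latter (91.5%). On 4 arrays (both at 4 h, replicate 2 at 8 h and replicate 2 at 16 h) between 41.3% and 55.6% of the empty positions were above background in the treated channel, against 1.4% to 5.9% on the other 4. After filtering, 16413 probes entered the fit, 8295 of them with a gene name, for 8199 genes. The log ratios of 2 arrays of the same time correlated across probes with a median r of 0.38, and those of different times with a median r of 0.41, so arrays of the same time were no more alike than others; probes are not independent replicates. The number of arrays limits the precision: the median standard error (SE) was 0.27 for a single time and 0.14 for the average over times.

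The first comparison asked what PGJ2 changed over the whole course, as the mean of the 4 time points. Chaperone and oxidative stress genes were among the largest increases. HSPA6, an inducible HSP70 chaperone, rose 18.5-fold (log2 4.21, SE 0.23, n = 8 arrays), HMOX1, the haem-degrading enzyme haem oxygenase 1, rose 16.4-fold (log2 4.03, SE 0.33, n = 8), and HSPA1B, another inducible HSP70, rose 15.3-fold (log2 3.94, SE 0.25, n = 8). DDIT3, the stress transcription factor CHOP, rose 7.19-fold (log2 2.85, SE 0.27) and GDF15, a secreted stress cytokine, rose 5.75-fold (log2 2.52, SE 0.18), both with n = 8. RARRES2, which encodes the secreted protein chemerin, fell by 2.80 on the log2 scale (SE 0.16) and MTAP, an enzyme of methionine salvage, fell by 2.54 (SE 0.18), each with a negative ratio on all 8 arrays.

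Among 15891 probes tested with limma, 1975 (12.4%) passed a Benjamini-Hochberg adjusted p of 0.05, 1106 higher and 869 lower, and 348 of them changed at least 2-fold. With median centring in place of loess the balance turned, with 1018 higher and 1217 lower, so the share of increases was 45.5% in place of 56.0%. With only probes above background on all 8 arrays it was 49.4% (709 higher and 726 lower). Leaving out 1 array lowered the count to 1152 or 1192 (4 h replicate 1 or 2), 1094 or 1063 (8 h), and 1234 or 1031 (16 h); it was 1472 without 24 h replicate 1 and did not fall without 24 h replicate 2 (1982). Beside the genes above, the largest increases included RAB13, a small GTPase of vesicle traffic, which was at least 27.1-fold higher because its spot was saturated in the treated channel on all 8 arrays. CACNA1B, a neuronal calcium channel subunit, rose by log2 3.80 (SE 0.22), with saturation on 2 arrays. HSPH1, an HSP110 chaperone, rose by 2.39 (SE 0.23, n = 7) and AADAC, an esterase, by 2.05 (SE 0.13, n = 7). CBFA2T2, a transcriptional corepressor, had a log2 ratio of 2.69 by its brightest probe but -0.23 by its other probe. ZBTB6, a zinc finger protein, and MCTS1, a translation factor, rose by 1.98 and 1.95. Other large decreases were those of PCDHA9, a protocadherin (log2 -2.33), KDM4D, a histone demethylase (-1.85), CLDN1, a tight junction protein (-1.79), KLRG1 (-1.60), ACOT7, an acyl-CoA thioesterase (-1.56), and CRYBB1, a crystallin (-1.53). The call of ACOT7 was lost without 4 h replicate 1 or either 8 h array (-1.64 to -1.45). HSPA1A, a near-identical copy of HSPA1B, was not measured in the fit, and related HSP70 transcripts can hybridise to each other's probes.

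The heat shock chaperones, targets of the transcription factor HSF1, had a median log2 ratio of 0.72. Of 25 measured members 11 rose, none fell and 14 did not pass; adjusted over the list alone, 16 rose and 1 fell. Besides HSPA6 and HSPA1B, HSPA4L, an HSP110-related chaperone, rose by log2 1.57 (SE 0.15) and HSPE1, the mitochondrial HSP10, by 1.55 (SE 0.15). DNAJB1, an HSP40 co-chaperone, had a ratio of -0.16 (SE 0.15) that did not pass. The list's shift against all other genes passed limma's camera test with a preset correlation (Benjamini-Hochberg adjusted p = 1.13e-07), and did not pass with a correlation estimated from the arrays (adjusted p = 0.392 with an estimated correlation).

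The targets of ATF4, the transcription factor of the integrated stress response, had a median log2 ratio of 0.64. Of 23 members 12 rose and 1 fell, and 10 did not pass; adjusted over the list alone, 14 rose and 1 fell. CEBPG, a leucine zipper transcription factor, rose by log2 1.19 (SE 0.20), and HERPUD1, a protein of endoplasmic reticulum quality control, by 1.11 (SE 0.15). The member that fell was TARS1, a threonyl-tRNA synthetase named after its value was seen (log2 -0.42, SE 0.12). ATF3, a stress-induced transcription factor, had a ratio of 1.36 with an SE of 0.50 and did not pass. The p53 and growth arrest genes had a median of 0.78, with 8 of 17 higher and none lower, or 11 higher and none lower adjusted over the list alone. GADD45A, a growth arrest gene, rose by 1.35 (SE 0.17), TNFRSF10B, a death receptor for TRAIL, by 1.77 (SE 0.29), PPM1D, a phosphatase, by 1.12 (SE 0.14) and BTG2, an antiproliferative factor, by 0.86 (SE 0.10). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose by 0.91 (SE 0.25), a call lost under 11 of 25 alternatives. Among them were the replicate number as a block, an offset of 10 and spot medians. Leaving out any 1 array except 8 h replicate 1 or 24 h replicate 2 also lost it (0.66 to 0.95). Both lists passed camera with limma (Benjamini-Hochberg adjusted p = 1.64e-07 for ATF4 targets and 0.000215 for p53 targets), and each had an adjusted p = 0.392 with an estimated correlation.

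Targets of NRF2, the transcription factor of the antioxidant and electrophile response, had a median log2 ratio of 0.45. Of 28 members 11 rose, none fell and 17 did not pass; adjusted over the list alone, 14 rose and 1 fell. GCLM, a subunit of the enzyme that limits glutathione synthesis, rose 3.77-fold (log2 1.92, SE 0.23, n = 7), and NQO1, a quinone reductase, rose 3.36-fold (log2 1.75, SE 0.11, n = 8). TXN, thioredoxin, rose by log2 0.89 (SE 0.10), and TXNRD1, its reductase, by 1.05 (SE 0.21), a call lost without 4 h replicate 2 (0.98). SQSTM1, the autophagy receptor p62, rose by 1.78 (SE 0.30). The list passed camera with limma (Benjamini-Hochberg adjusted p = 1.25e-06), with an adjusted p = 0.392 with an estimated correlation.

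Both lists of proteasome subunit genes were called higher with a preset correlation, and neither was with an estimated one (adjusted p = 0.392 for both, with an estimated correlation). For the 19S regulatory particle, which recognises and unfolds ubiquitinated proteins, the median log2 ratio was 0.48, and 9 of 17 genes rose, none fell and 8 did not pass; adjusted over the list alone, 15 rose. PSMC5, an ATPase subunit, rose by 1.43 (SE 0.11), PSMD12 by 0.90 (SE 0.15), PSMD1 by 0.86 (SE 0.10) and PSMD6 by 0.82 (SE 0.15). PSMD14, the deubiquitinase subunit, had a ratio of 0.48 (SE 0.20) that did not pass, and PSMC4 was measured on 4 arrays, none at 8 h, with 0.26, 0.54 and 0.41 at 4, 16 and 24 h. For the 20S core, which degrades the proteins, the median was 0.40, and 7 of 11 genes rose, none fell and 4 did not pass; adjusted over the list alone, 8 rose. Those that rose included PSMB7 (1.11, SE 0.12), PSMA5 (0.89, SE 0.14), PSMB2 (0.87, SE 0.16) and PSMA3 (0.69, SE 0.12). Camera with limma gave a Benjamini-Hochberg adjusted p = 1.57e-07 for the 19S and 3.97e-05 for the 20S list. Of 28 genes for ubiquitin and deubiquitination, 7 rose and none fell, or 10 rose and 2 fell adjusted over the list alone. Among them UFD1, a cofactor of the VCP ATPase, rose by 0.74 (SE 0.12), and RPS27A, which encodes ubiquitin fused to a ribosomal protein, by 0.52 (SE 0.11), a call lost without 4 h replicate 2, either 8 h array or 16 h replicate 2 (0.46 to 0.52). UBE2H, a conjugating enzyme, rose by 0.54 (SE 0.11) but had a ratio of -0.01 without background correction, and without 16 h replicate 2 its call was lost (0.52). UCHL1, a neuronal deubiquitinase, rose by 0.63 (SE 0.15), a call lost under 9 of 24 alternatives, among them leaving out any 1 array except the second replicates of 16 and 24 h (0.49 to 0.68). The ubiquitin list's median of 0.12 was near the threshold (limma camera, Benjamini-Hochberg adjusted p = 0.0461; adjusted p = 0.392 with an estimated correlation), and with median centring it was -0.01 and not called. The call was also lost without 4 h replicate 2 (median 0.12), 8 h replicate 2 (0.24), 16 h replicate 2 (0.20) or 24 h replicate 1 (0.15). A term for arrays with signal at empty positions removed it too (limma camera, adjusted p = 0.0548).

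Both lists of DNA replication and cell division genes were called lower with a preset correlation, and neither was with an estimated one (adjusted p = 0.392 for both, with an estimated correlation). Of 35 genes for the G1/S transition and DNA replication, 16 fell, 1 rose and 18 did not pass, or 21 fell and 1 rose adjusted over the list alone, with a median log2 ratio of -0.54. PCNA, the replication clamp, fell by 1.34 (SE 0.15), E2F1, a transcription factor of S phase entry, by 1.25 (SE 0.15), MCM2, a helicase subunit, by 0.95 (SE 0.13), and RFC3, a clamp loader subunit, by 0.92 (SE 0.13). Of 32 genes for G2/M and mitosis, 8 fell, 1 rose and 23 did not pass, or 12 fell and 1 rose adjusted over the list alone, with a median of -0.35. STMN1, a microtubule-destabilising protein, fell by 0.97 (SE 0.13), CENPA, the centromeric histone, by 0.84 (SE 0.15) and KIF20A, a mitotic kinesin, by 0.83 (SE 0.15). AURKB, a mitotic kinase, rose by 1.24 (SE 0.14, n = 7), and without background correction, or with spots not found kept, its call was lost. Camera with limma gave a Benjamini-Hochberg adjusted p = 1.13e-07 for G1/S and 0.000171 for G2/M.

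Markers of adrenergic neuroblastoma cells, with a median log2 ratio of -0.82, were called lower as a list with a preset correlation and not with an estimated one (adjusted p = 0.392 with an estimated correlation). Of 21 members 12 fell, 1 rose and 8 did not pass, or 14 fell and 2 rose adjusted over the list alone. DBH and DDC, enzymes of catecholamine synthesis, fell by 1.58 (SE 0.21) and by 1.35 (SE 0.12), and GATA2, a transcription factor, fell by 1.69 (SE 0.19). CHRNA3, a nicotinic receptor subunit, fell by 0.87 (SE 0.12). The member that rose was SLC18A1, a vesicular monoamine transporter named after its value was seen (log2 0.97, SE 0.17). Camera with limma gave a Benjamini-Hochberg adjusted p = 2.72e-06. Markers of mesenchymal neuroblastoma cells did not pass as a group (median -0.23, adjusted p = 0.348). Among 15 of them TWIST1, a transcription factor, fell by 1.31 (SE 0.18), SOX9, another, rose by 1.14 (SE 0.18), and VIM, vimentin, had a ratio of 0.25 (SE 0.12) that did not pass. In all 1 rose and 4 fell, or 2 and 5 adjusted over the list alone.

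The remaining called lists had smaller medians. Of 52 respiratory chain genes 11 fell and none rose, or 14 and none adjusted over the list alone (median -0.17), among them the ATP synthase subunits ATP5MC1 (log2 -1.19, SE 0.13) and ATP5F1D (-0.85, SE 0.12) and the complex I subunits NDUFA2 (-0.79, SE 0.12) and NDUFS5 (-0.72, SE 0.12). Of 23 autophagy and lysosome genes 7 rose and 1 fell, the same adjusted over the list alone (median 0.23). They included CTSL, a lysosomal protease (1.27, SE 0.25, n = 6), LAMP1, a lysosomal membrane protein (1.08, SE 0.18, n = 7), and NBR1, an autophagy receptor (0.58, SE 0.11). The call of CTSL was lost with print-tip loess (0.94), with spots not found kept (0.83) and in the deposited ratios (1.49), and that of NBR1 with print-tip loess (0.34) and in the deposited ratios (0.67). The one that fell was GABARAP, named after its value was seen (-0.42, SE 0.10). Of 23 extracellular matrix and TGF-beta target genes 6 fell and 1 rose, or 6 and 2 adjusted over the list alone (median -0.23): COL3A1, a collagen, fell by 1.08 (SE 0.25; call lost without any 1 of the 4 and 16 h arrays, -1.12 to -1.03), SPARC by 0.72 (SE 0.14) and LUM, a proteoglycan, by 0.66 (SE 0.12), while TIMP1, a metalloproteinase inhibitor, rose by 0.81 (SE 0.10). Camera with limma gave Benjamini-Hochberg adjusted p-values of 0.000313, 0.00742 and 0.0248 for these 3 lists, each with an adjusted p = 0.392 with an estimated correlation. The autophagy call was lost without 8 h replicate 2 (adjusted p = 0.0740), and the matrix call without 8 h replicate 2 (0.0737), 16 h replicate 1 (0.0702) or 24 h replicate 1 (0.116). None of the 13 list calls, 8 up and 5 down, held with the estimated correlation, which was taken on probes measured on all arrays. On those probes the autophagy and matrix calls were lost with the preset correlation too (adjusted p = 0.0515 and 0.0670). By fry, a limma test of whether a set's own genes move, on balance, one way, 12 of these 13 had an adjusted p under 0.05 and the matrix list 0.0617; so did 8 lists that camera did not call.

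**Figure D1:**
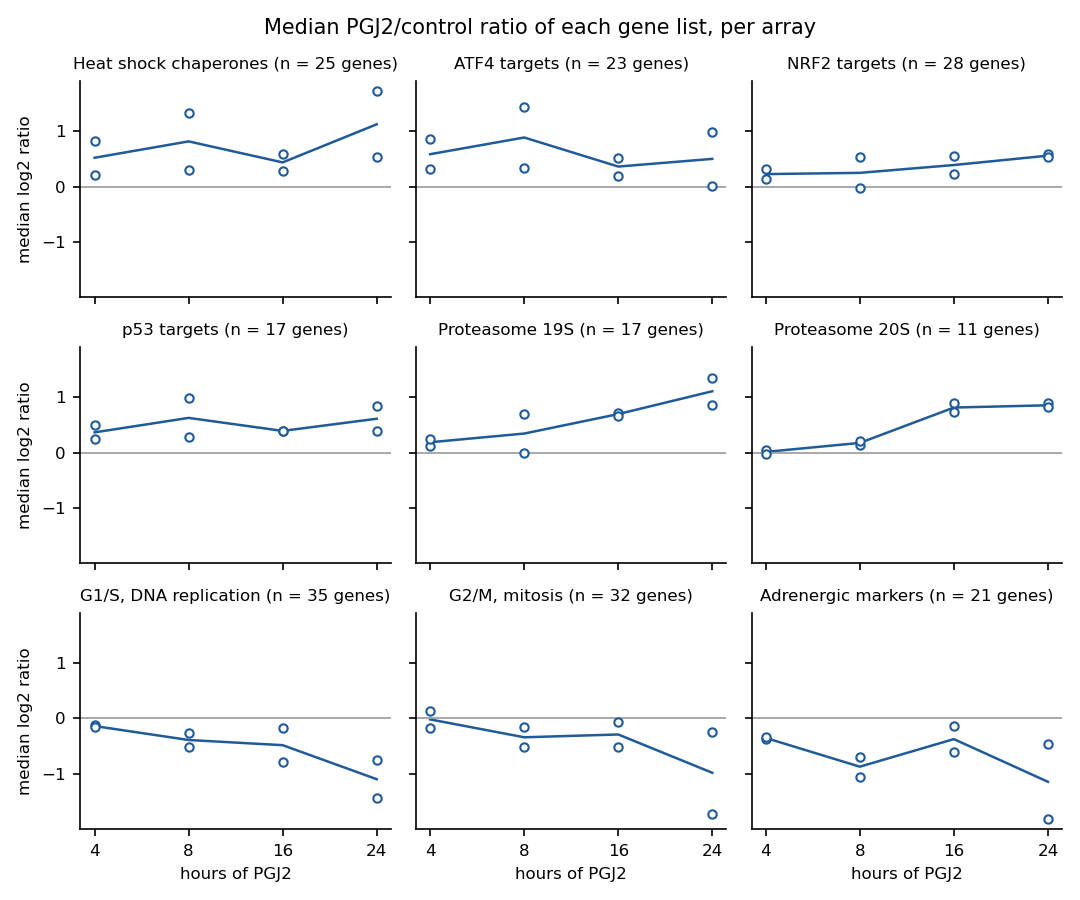
Median log2 ratio of treated over vehicle cells (vertical axis) in 9 gene lists against hours of PGJ2 (horizontal axis, times evenly spaced). Each point is the median on 1 array, lines join the means of the 2 arrays per time, and n is the number of genes tested in the average. The 20S medians lie between -0.02 and 0.21 on the 4 arrays at 4 and 8 h and between 0.72 and 0.90 on the 4 at 16 and 24 h.

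Among the lists that did not pass camera, some members did pass limma's test. Of 26 immediate early and AP-1 genes 7 rose and 4 fell, or 9 and 5 adjusted over the list alone (adjusted p = 0.0777), with increases of DUSP5, a MAP kinase phosphatase (log2 1.67, SE 0.20, n = 7), and FOSL1, an AP-1 subunit (1.44, SE 0.15). Of 13 endoplasmic reticulum chaperone genes 4 rose and 1 fell, or 5 and 1 adjusted over the list alone (adjusted p = 0.25). DNAJB11, a cofactor of the chaperone BiP, rose by 1.25 (SE 0.19), and XBP1, a transcription factor of the unfolded protein response, by 1.10 (SE 0.16), while MANF, a secreted protein named after its value was seen, fell by 0.74 (SE 0.12). HSPA5, which encodes BiP itself, was not measured in the fit. Of 23 hypoxia and glycolysis genes 4 rose and 4 fell, or 6 and 6 adjusted over the list alone (adjusted p = 0.994; the median was -0.02 and the mean 0.06): BNIP3, a mitophagy receptor, rose by 1.10 (SE 0.14) and LDHA, lactate dehydrogenase, fell by 1.02 (SE 0.15). Of 20 cholesterol synthesis genes 5 fell and 1 rose, or 6 and 3 adjusted over the list alone (adjusted p = 0.127), with EBP, a sterol isomerase, at -1.14 (SE 0.13) and MSMO1, a sterol oxidase, at -0.55 (SE 0.12; call lost without 4 h replicate 1, either 8 h array or 16 h replicate 2, -0.56 to -0.50). Of 24 apoptosis regulators 3 rose and none fell, the same adjusted over the list alone (adjusted p = 0.127), among them XIAP, a caspase inhibitor (0.55, SE 0.12), and BID, a BH3 protein (0.44, SE 0.10). The call of XIAP was lost without the first replicate of 4, 8 or 16 h or 16 h replicate 2 (0.51 to 0.58), and that of BID without any 1 array of 4, 8 or 16 h (0.41 to 0.46).

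Of 29 neuronal cytoskeleton and synapse genes 2 rose and 2 fell, or 2 and 3 adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.127). CHGB, a granin of secretory vesicles, fell by 0.82 (SE 0.14) and SCG2, another granin, rose by 0.68 (SE 0.15; call lost without either 4 h array, 8 or 16 h replicate 1 or 24 h replicate 2, 0.52 to 0.71). Tau (MAPT, log2 -0.27, SE 0.21) did not pass. Of 24 neurodegeneration-linked genes 4 rose and 1 fell, or 8 and 1 adjusted over the list alone (adjusted p = 0.127), and SOD1, superoxide dismutase, rose by 1.07 (SE 0.17). Of 19 tubulin and actin genes 1 rose and 3 fell, or 1 and 6 adjusted over the list alone (adjusted p = 0.129), with CFL1, cofilin, at -0.76 (SE 0.10) and TUBB4A, a beta-tubulin, at 0.69 (SE 0.16; call lost without 4 h replicate 1, 8 h replicate 2, either 16 h array or 24 h replicate 1, 0.56 to 0.71). Of 17 inflammatory and NF-kB targets 1 rose and 3 fell, or 1 and 5 adjusted over the list alone (adjusted p = 0.443). CCL20, a chemokine, rose by 0.89 (SE 0.17). CCL5, another chemokine, was not well above background in treated cells on any array and was at least 1.38-fold lower there, a call lost without any 1 array except 8 h replicate 1 or 24 h replicate 2 (log2 -0.52 to -0.41). PTGS2, the inducible cyclooxygenase, had a ratio of -0.06 (SE 0.16). Of 55 cytosolic ribosomal protein genes 5 rose and 2 fell, the same adjusted over the list alone (adjusted p = 0.339).

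Of 16 targets of PPARG, a nuclear receptor, 1 rose and 1 fell, the same adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.848). ANGPTL4, a lipase inhibitor, rose by 0.72 (SE 0.15), and its call was lost without background correction (0.33), in the deposited ratios (0.74), without 8 h replicate 1 (0.71) and with the 2 dimmest arrays left out (0.67). Of 11 fatty acid synthesis genes 1 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.805): ME1, malic enzyme, rose by 1.24 (SE 0.25) and SCD, a desaturase, fell by 0.59 (SE 0.13), calls lost without 4 h replicate 2 for ME1 (1.2) and without 4 h replicate 1, 8 h replicate 2 or 16 h replicate 1 for SCD (-0.56 to -0.54). Of 21 ribosome biogenesis genes 2 rose and none fell, the same adjusted over the list alone (adjusted p = 0.916), namely NOB1 (0.70, SE 0.14) and POLR1C (0.70, SE 0.18), while the list's median was -0.04 and its mean 0.03. The call of NOB1 was lost without either 16 h array (0.69 and 0.72), and that of POLR1C without any 1 array except 16 h replicate 1 or 24 h replicate 1 (0.53 to 0.74). Of 7 proteasome assembly factors and activators POMP, a 20S assembly chaperone, alone rose (0.54, SE 0.15; call lost without any 1 array except 8 or 24 h replicate 2, 0.46 to 0.62), with 1 higher and 1 lower adjusted over the list alone (adjusted p = 0.848). Of 7 immunoproteasome and antigen processing genes B2M, the light chain of MHC class I, alone rose (0.62, SE 0.16; call lost without any 1 array except 8 h replicate 1, 0.43 to 0.69), the same adjusted over the list alone (adjusted p = 0.410). None of the 13 prostaglandin synthesis and receptor genes passed limma's test, also adjusted over the list alone (adjusted p = 0.848), with an unadjusted p under 0.05 for PTGER1 (0.53, SE 0.16) and TBXAS1 (-0.43, SE 0.13). Markers of other cell types did not pass as groups: among 11 blood cell genes CD3D alone passed (-1.07, SE 0.17; adjusted p = 0.845 for the list), and among 7 Schwann cell and melanocytic genes none did (adjusted p = 0.845), with PMP22 at -0.35 (SE 0.13) and MBP at -0.11 (SE 0.13), and the counts were the same adjusted over the list alone. Of the metallothioneins 2 were measured, too few for a test of the list, and neither MT2A (-0.48, SE 0.17) nor MT3 (-0.23, SE 0.15) passed.

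Beside the losses already given, some calls of genes named above with their averaged ratios were lost under other processing. In the deposited ratios, where fewer probes were tested, they were those of ACOT7, B2M, BID, CEBPG, CFL1, CHGB, LUM, MCM2, MSMO1, NDUFA2, NDUFS5, POLR1C, SCD, SPARC and UBE2H. With print-tip loess they were those of CCL5, MSMO1, NOB1, POLR1C, POMP, RPS27A and SCG2, and with median centring those of B2M, BID, CCL5, CDKN1A, POMP, RPS27A, SCG2, TUBB4A, UCHL1 and XIAP. Without background correction they were those of CCL5 and POMP, with a term for arrays with signal at empty positions that of COL3A1, and with the 2 dimmest arrays left out those of ACOT7, BID, NOB1, POLR1C, POMP, PSMB2, RPS27A, SCG2, UBE2H, UCHL1 and XIAP.

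The next comparisons took each time alone. At 4 h, 12 probes were higher and 3 lower among 16385 tested (limma, Benjamini-Hochberg adjusted p under 0.05). They included HSPA1B (log2 3.74, SE 0.49, n = 2), RAB13 (4.58, SE 0.36, saturated), CACNA1B (4.70, SE 0.44), CHMP1A, a subunit of the ESCRT membrane scission complex (2.16, SE 0.30), and MAGEC2, a cancer-testis antigen (1.91, SE 0.24), with RARRES2 (-2.76, SE 0.32) and MTAP (-2.62, SE 0.36) among the lower. Of the lists, heat shock chaperones (median 0.63), ATF4 targets (0.49), p53 targets (0.46), NRF2 targets (0.24) and ribosomal proteins (0.17) were called higher and adrenergic markers (-0.37) lower, each with an adjusted p = 0.924 with an estimated correlation. The medians on replicates 1 and 2 were 0.21 and 0.83 for heat shock chaperones, 0.31 and 0.86 for ATF4 targets, 0.24 and 0.49 for p53 targets, 0.14 and 0.31 for NRF2 targets and 0.10 and 0.25 for ribosomal proteins. With a term for arrays with signal at empty positions, which both 4 h arrays had, the heat shock median was 0.21, and the calls of p53 targets (median 0.22, adjusted p = 0.488) and ribosomal proteins (adjusted p = 0.0799) were lost. Every array mattered to the count of probes: it was 95 without 4 h replicate 2 (13 higher and 82 lower), 3 without 4 h replicate 1 or either 8 h array, 9 without either 16 h array, 28 without either 24 h array, and 1 with that term. Print-tip loess gave 15 higher and 1 lower.

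At 8 h, 33 probes were higher and 11 lower among 16260 tested (limma, Benjamini-Hochberg adjusted p under 0.05). HSPA6 rose by log2 4.78 (SE 0.46, n = 2), HSPA1B by 4.23 (SE 0.49) and GDF15 by 3.26 (SE 0.36), while PCNA fell by 1.88 (SE 0.29), TUBB7P, a tubulin pseudogene, by 1.58 (SE 0.25) and SLC52A1, a riboflavin transporter, by 1.45 (SE 0.23). The called lists were ATF4 targets (median 0.89), heat shock chaperones (0.88), p53 targets (0.70), NRF2 targets (0.35), the 19S particle (0.31) and immediate early genes (0.16) on the higher side. On the lower side they were adrenergic markers (-0.86), G2/M (-0.40), G1/S (-0.29), the respiratory chain (-0.22) and tubulin and actin genes (-0.14), and each of the 11 had an adjusted p = 0.453 with an estimated correlation. The medians of the higher lists were larger on replicate 2, and those of NRF2 targets, the 19S particle and immediate early genes were positive on replicate 2 alone. Replicate 1 had the smallest share of probes above background in the treated channel (28.3%), and whether this lowered its ratios was not tested. On replicates 1 and 2 the medians were 0.34 and 1.43 for ATF4 targets, 0.31 and 1.33 for heat shock chaperones, 0.27 and 0.97 for p53 targets, -0.03 and 0.53 for NRF2 targets, -0.0022 and 0.69 for the 19S particle and -0.16 and 0.36 for immediate early genes. They were -0.69 and -1.05 for adrenergic markers, -0.26 and -0.52 for G1/S, -0.17 and -0.52 for G2/M and -0.27 and -0.07 for tubulin and actin genes. With a term for arrays with signal at empty positions the calls of immediate early genes (adjusted p = 0.0585) and of tubulin and actin genes (0.0696) were lost. The count of probes fell to 2 without 8 h replicate 1, to 1 without 8 h replicate 2, to 18 without either 4 h array and to 25 without 16 h replicate 2, and rose to 81 or 83 without 24 h replicate 1 or 2. The balance of 33 higher and 11 lower became 32 and 65 with median centring, 21 and 3 with print-tip loess and 119 and 68 with ratios scaled between arrays.

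At 16 h, 23 probes were higher and 4 lower among 16381 tested (limma, Benjamini-Hochberg adjusted p under 0.05). HSPA6 rose by log2 4.16 (SE 0.46, n = 2), GDF15 by 2.65 (SE 0.36), AADAC by 2.28 (SE 0.23), NQO1 by 2.20 (SE 0.23) and PSMD1 by 1.47 (SE 0.21). NPDC1, a neural membrane protein, fell by 1.43 (SE 0.20), beside RARRES2 (-2.75, SE 0.32) and MTAP (-2.61, SE 0.36). The lists called higher were the 20S core (median 0.83), the 19S particle (0.52), p53 targets (0.45), NRF2 targets (0.42), heat shock chaperones (0.40), ATF4 targets (0.36) and autophagy genes (0.19). Those called lower were G1/S (-0.53), adrenergic markers (-0.40), G2/M (-0.35), cholesterol synthesis (-0.28) and the respiratory chain (-0.20), and the 12 had an adjusted p between 0.215 and 0.545 with an estimated correlation. On replicates 1 and 2 the medians were -0.79 and -0.17 for G1/S, -0.51 and -0.07 for G2/M, -0.62 and -0.13 for adrenergic markers, -0.12 and -0.34 for the respiratory chain, 0.29 and 0.59 for heat shock chaperones, 0.53 and 0.20 for ATF4 targets, 0.54 and 0.24 for NRF2 targets and 0.23 and -0.02 for autophagy genes. The count of probes was 1 without 16 h replicate 2 and 64 without 16 h replicate 1 (25 higher and 39 lower), 16 without either 4 h array and 9 or 11 without 8 h replicate 1 or 2. Print-tip loess gave 17 higher and 6 lower, and ratios scaled between arrays gave 51 and 20.

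At 24 h, 327 probes were higher and 210 lower among 16076 tested (limma, Benjamini-Hochberg adjusted p under 0.05), and 510 of the 537 changed at least 2-fold. HSPA6 rose by log2 5.51 (SE 0.46, n = 2), HSPA1B by 4.70 (SE 0.49), HMOX1 by 4.22 (SE 0.66), GDF15 by 3.25 (SE 0.36) and PSMC5 by 3.08 (SE 0.22). DBH fell by 2.67 (SE 0.41), PCDHA9 by 2.42 (SE 0.54) and RRM2, a ribonucleotide reductase subunit, by 2.36 (SE 0.49). The lists called higher were the 19S particle (median 0.97), heat shock chaperones (0.97), the 20S core (0.95), ATF4 targets (0.91), p53 targets (0.79), NRF2 targets (0.57), autophagy (0.51), ubiquitin (0.33), apoptosis (0.24) and neurodegeneration-linked genes (0.17). Those called lower were adrenergic markers (-1.14), G1/S (-1.0), G2/M (-0.91), extracellular matrix (-0.42) and the respiratory chain (-0.20), and the 15 had an adjusted p between 0.263 and 0.432 with an estimated correlation. Replicate 1 carried much of this: on replicates 1 and 2 the medians were 0.99 and 0.0097 for ATF4 targets, 1.72 and 0.53 for heat shock chaperones, 1.34 and 0.86 for the 19S particle, 0.84 and 0.38 for p53 targets, 0.73 and 0.34 for autophagy, 0.45 and 0.11 for ubiquitin genes, 0.34 and 0.07 for neurodegeneration-linked genes and 0.34 and 0.12 for apoptosis genes. They were -1.82 and -0.47 for adrenergic markers, -1.44 and -0.76 for G1/S, -1.72 and -0.24 for G2/M, -0.67 and -0.22 for matrix genes and -0.34 and -0.04 for the respiratory chain. For the 20S core (0.88 and 0.82) and NRF2 targets (0.59 and 0.53) the replicates were closer. The apoptosis call was lost with a term for arrays with signal at empty positions (adjusted p = 0.199). The count of probes was 50 without 24 h replicate 1, 274 to 334 without 16 h replicate 2 or any 1 of the 4 and 8 h arrays, and 93 with that term. Median centring gave 299 higher and 290 lower, ratios scaled between arrays 27 and 9, and the deposited ratios 200 and 200. Without 24 h replicate 2 the balance turned, with 234 higher and 257 lower.

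**Figure D2:**
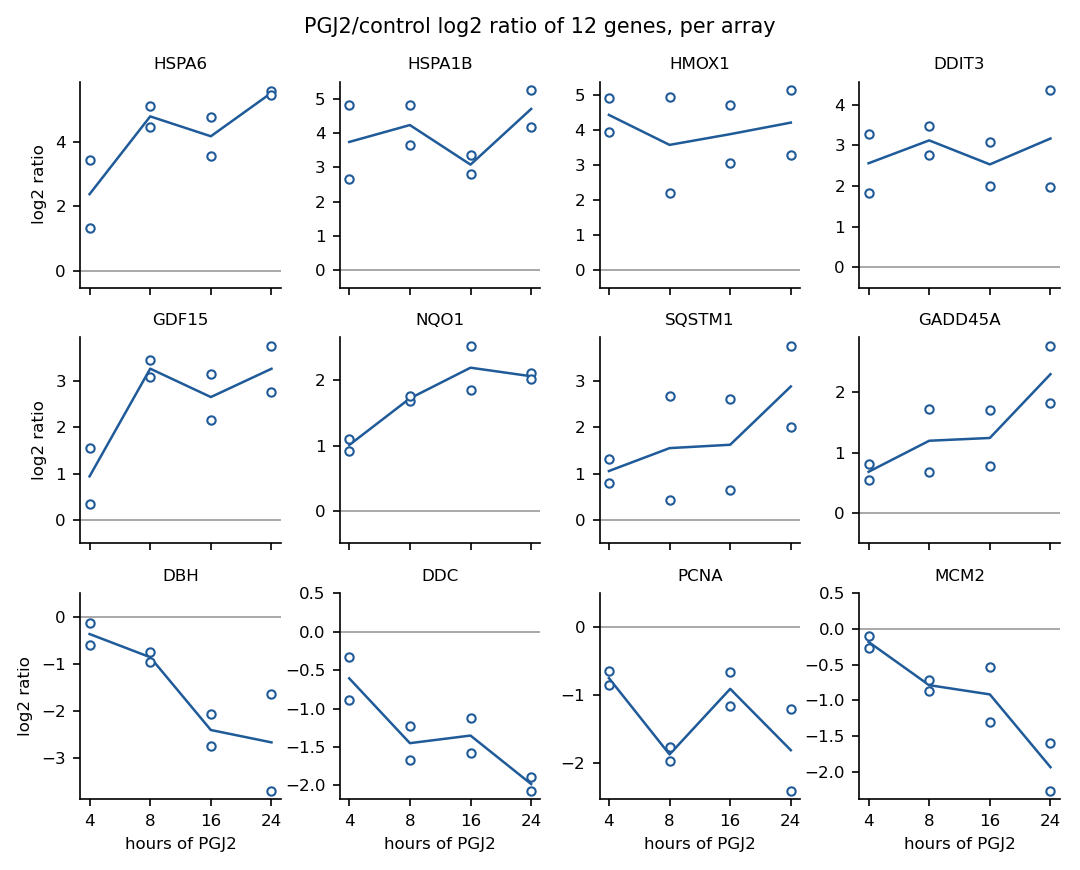
Log2 ratio of treated over vehicle cells (vertical axis, own scale per gene) against hours of PGJ2 (horizontal axis, times evenly spaced) for 12 genes picked from those named here. Each point is 1 array and lines join the means of the 2 arrays per time; the mean of HSPA6 went from 2.38 at 4 h to 5.51 at 24 h and that of DBH from -0.37 to -2.67.

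The calls at different times overlapped, each time having its own control cells. Of the 15 probes called at 4 h, 12 were also called at 8 h with the same sign, where independent lists would share 0.0406, and 33 of the 44 at 8 h were called at 24 h, against 1.48. A constant dye effect would add to this overlap. So would the spread estimate of each probe, which the tests of all times shared. The figures for independent lists are therefore too low a comparison. Of the probes called at 24 h and measured at every time, 88.9% had the same sign at 4 h, 91.5% at 8 h and 94.2% at 16 h, and the median ratio relative to that at 24 h was 0.26, 0.39 and 0.46. These probes were selected for their 24 h values, which makes the earlier ratios look smaller.

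The last comparison asked whether the effect moved with time, as the mean of 16 and 24 h minus the mean of 4 and 8 h. The proteasome subunit genes moved most among the called lists, although no list passed with an estimated correlation. The 19S list was higher late by a median log2 of 0.63 (17 genes) and the 20S list by 0.77 (11 genes), and 26 of the 28 subunits had a larger ratio late, with a median of 0.25 early and 0.78 late. Examples are PSMD1 (1.17, SE 0.21), PSMA5 (1.15, SE 0.27), PSMB7 (1.07, SE 0.25), PSMC5 (1.06, SE 0.22), PSMD6 (0.92, SE 0.30), PSMB3 (0.90, SE 0.22), SEM1 (0.90, SE 0.20) and PSMB4 (0.87, SE 0.20), each over 8 arrays. No single gene passed over all probes; adjusted over the list alone, 3 of the 19S genes were higher late, and 7 of the 20S genes were higher and 1 lower. The G1/S list (median -0.46) and the G2/M list (-0.37) were lower late, with CDC45, a replication helicase factor, at -1.10 (SE 0.36), MCM2 at -0.94 (SE 0.26), MCM6 at -0.85 (SE 0.27), RFC4 at -0.73 (SE 0.27), PLK1, a mitotic kinase, at -1.23 (SE 0.43, n = 6), STMN1 at -0.90 (SE 0.27) and HMMR at -0.86 (SE 0.32). AURKB went the other way (1.14, SE 0.27).

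Camera with limma gave Benjamini-Hochberg adjusted p-values of 4.58e-09 for the 19S list, 5.17e-09 for the 20S list, 4.07e-06 for G1/S and 0.00400 for G2/M. They did not pass otherwise: the adjusted p was 0.566, 0.127, 0.627 and 0.642 with an estimated correlation. Within the 4 arrays with signal at empty positions, of which 1 was late (16 h replicate 2), the median late minus early difference was 0.31 for the 19S and 0.65 for the 20S list, and within the other 4, of which 1 was early (8 h replicate 1), it was 0.99 and 0.87. For G1/S it was 0.09 and -0.60, and for G2/M 0.11 and -0.30. Each of these differences sets 3 arrays against a single one, and 16 h replicate 2 was the late array with the smallest cell cycle ratios (medians of -0.17 for G1/S and -0.07 for G2/M). The G2/M call was lost with a term for these arrays (limma camera, adjusted p = 0.206). It was also lost without 16 h replicate 1 (median -0.29) or 24 h replicate 1 (median -0.04). Those 2 replicates had the lowest cell cycle medians of the late arrays. They were also the only arrays with no spot outside the scanned image, and whether they form a batch was not tested.

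Smaller shifts were called for 4 more lists, none of which passed with an estimated correlation. NRF2 targets were higher late (median 0.16), with BLVRB, biliverdin reductase B (0.96, SE 0.31), SOD1 (0.89, SE 0.34), TXN (0.81, SE 0.20) and NQO1 (0.76, SE 0.23) as examples. Ubiquitin genes (0.24) and neurodegeneration-linked genes (0.17) were higher, both lists holding VCP, an ATPase that extracts ubiquitinated proteins (1.07, SE 0.33), beside UBQLN1, a proteasome shuttle factor (1.07, SE 0.42), and TARDBP, the RNA-binding protein TDP-43 (0.85, SE 0.20). RAD23B, another shuttle factor (-0.77, SE 0.25), and BACE1, the beta-secretase (-0.69, SE 0.31), had ratios that went the other way. Cytosolic ribosomal proteins were lower late (-0.16), with RPS19 (-0.91, SE 0.27), RPL10 (-0.74, SE 0.33), RPL36 (-0.73, SE 0.24) and RPS28 (-0.53, SE 0.24), of which RPL36 and RPS28 were saturated in the vehicle channel on 3 arrays. No gene of these 4 lists, nor of G1/S and G2/M, passed adjusted over the list alone. Camera with limma gave Benjamini-Hochberg adjusted p-values of 0.00482, 0.0405, 0.0344 and 0.00513 for NRF2, ubiquitin, neurodegeneration and ribosomal genes, against an adjusted p = 0.627, 0.633, 0.627 and 0.627 with an estimated correlation. Within the arrays with and without signal at empty positions the NRF2 difference was 0.01 and 0.66, each against a single array. The ribosomal call was lost with median centring (median 0.02), with print-tip loess (adjusted p = 0.139) and with a term for arrays with signal at empty positions (0.0530). The neurodegeneration call was lost with that term (0.143) and the ubiquitin call with print-tip loess (0.0593), both with the replicate number as a block (0.0645 for each), and the NRF2 call with the 2 dimmest arrays left out (0.0669). Each of these 4 calls was also lost when single arrays were left out. The NRF2 call was lost without 8, 16 or 24 h replicate 1 (medians of 0.20, 0.10 and 0.26). The ribosomal call was lost without 4 or 8 h replicate 2 (medians of -0.15 and -0.085). The ubiquitin call was lost without 4, 8, 16 or 24 h replicate 1 or 16 h replicate 2, with medians from 0.08 (24 h replicate 1) to 0.26 (16 h replicate 1). The neurodegeneration call was lost without any 1 array except the second replicates of 16 and 24 h, with medians from 0.096 (8 h replicate 2) to 0.19 (8 h replicate 1). In all, 8 lists were called, against 4 without 16 h replicate 1, 5 without 24 h replicate 1 and 12 without 24 h replicate 2.

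Among single probes, limma called 0 of 15891 for late minus early at a Benjamini-Hochberg adjusted p under 0.05, with 933 at an unadjusted p under 0.05 where chance gives 795. It called 0 for any difference between the 4 times by the moderated F test, with 4.0% of the 15891 probes at an unadjusted p under 0.05. Among 200 probes measured on all arrays, simulated 4-fold changes at the late times were recovered for 97.0% and 2-fold changes for 3.0%. Differences of 2-fold between early and late were thus mostly not detectable with these arrays.

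**Figure D3:**
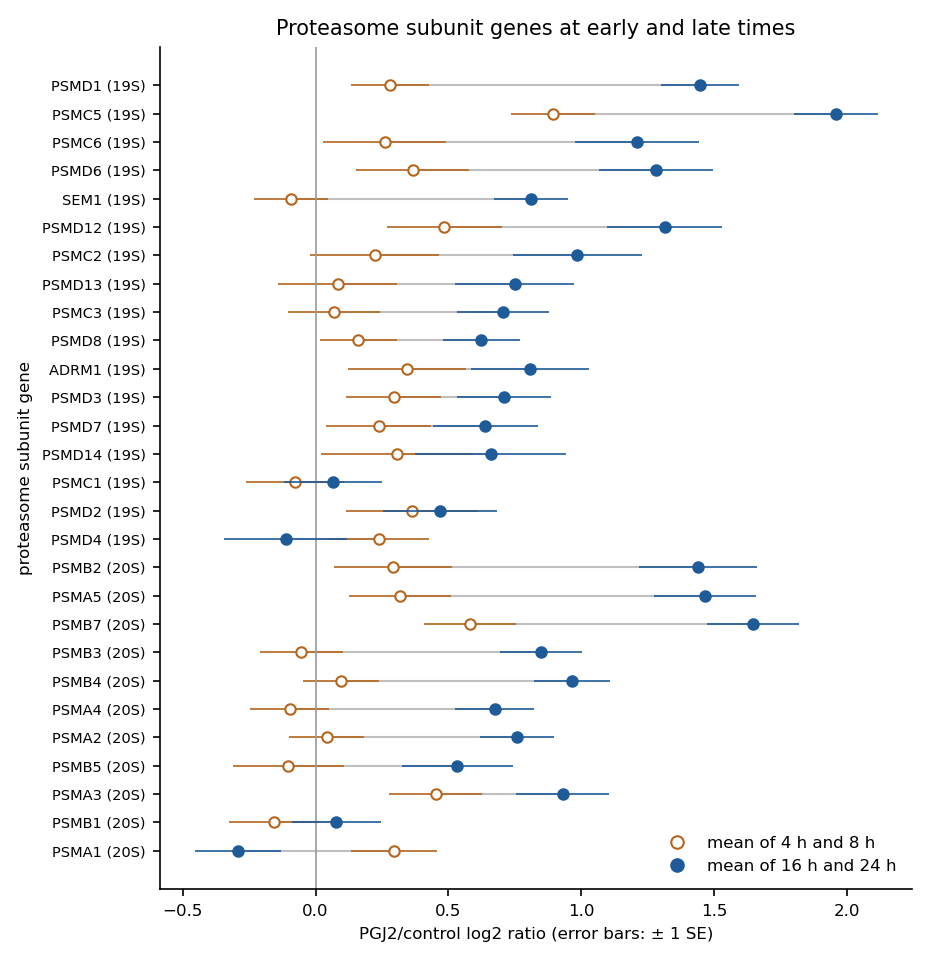
Log2 ratio of treated over vehicle cells (horizontal axis) for 28 proteasome subunit genes (vertical axis), as the mean of 4 and 8 h (open points) and of 16 and 24 h (filled points); bars are 1 standard error. For 26 of the 28 genes the late point lies to the right of the early one, the exceptions, named after their values were seen, being PSMA1 and PSMD4.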

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

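The tests of a constant dye effect for the first 2 patterns, of the arrays with signal at empty positions, of other splits for the proteasome genes and for the largest shift of any list, and of a changed share of cells were chosen only after the result was seen, as was that of the large ratios without a difference between times. The remaining tests in this part were chosen before.

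In 8 gene lists the effect of PGJ2 differed between the early times (4 and 8 h) and the late times (16 and 24 h), by a test of the difference itself with a preset correlation; no list passed with an estimated correlation. The late minus early median log2 ratio was 0.63 for the 19S regulatory particle, 0.77 for the 20S core, -0.46 for G1/S and DNA replication, -0.37 for G2/M and mitosis, 0.16 for NRF2 targets, -0.16 for cytosolic ribosomal proteins, 0.17 for neurodegeneration-linked genes and 0.24 for ubiquitin genes. Without 24 h replicate 1 the G2/M median was -0.04 and the ubiquitin median 0.08. Of the 35 splits of the 8 arrays into 4 and 4, 10 gave at least as many called lists as early against late, with 6 in the real split of this model and 14 in the highest other, so chance could not be excluded for the number of lists. The 14 lists may reflect a structure of the samples other than time or correlated genes, which was not tested; the split by signal at empty positions called 4. For single probes the real count by limma was 0 (957 at an unadjusted p under 0.05), as was the highest other, so all 35 splits gave as many and the count says nothing about chance.

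The higher ratios of the proteasome subunit genes at late than at early times, a median log2 difference of 0.69 (SE 0.11) over 28 genes, was weighed as the first pattern. A constant dye effect cancels in this difference by the design; no value tested it apart from the difference itself, for which the genes were picked. The median lay at percentile 100 of 10000 random lists of the same size and brightness, whose central 95% ran from -0.17 to 0.14, which argues against a brightness bias. With a term for the arrays with signal at empty positions the median was 0.79, which argues against these arrays. Within them and within the others it was 0.39 and 0.91, each against a single array. The lowest late array lay 0.37 above the highest early one, so the difference did not rest on a few arrays alone. Picking genes for their shift favours such a separation, which therefore does not bear on chance. Chance stays open: the difference was as large in 1 of 35 splits, the real one (0.69, highest other 0.56), but these genes were picked for their shift, and the largest shift of any list was as large in 2 of 35 (real 0.77, highest other 0.79), so a biological rise with longer exposure may be no more than a hypothesis.

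The second pattern was the negative median ratio of the adrenergic marker genes (-0.82), which lay at percentile 0 of random lists of the same brightness (central 95% from -0.20 to 0.14), which argues against a brightness bias. A smaller share of adrenergic cells among the attached cells could lower these markers and raise those of mesenchymal cells, but the mesenchymal median was -0.23 with an SE of 0.19, which decides neither way. A constant dye effect also stays open, since the late minus early median of the adrenergic list was -0.11 (SE 0.16). Lower expression within the cells after PGJ2 stays open as the biological explanation.

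The third pattern was that the largest averaged ratios were alike at every time, as a constant dye or probe effect would make them. Of the 24 genes with the largest ratios, 6 differed between times at an unadjusted p under 0.05 by the moderated F test (AADAC, CACNA1B, DBH, GDF15 and HSPA6 among them). That is more than ratios alike at every time would give by chance if the genes were independent. They share the same 8 arrays, and the count was not tested as a set. None passed after adjustment (moderated F test, Benjamini-Hochberg adjusted p = 0.998 for each). CACNA1B was saturated on some arrays, and an effect that varied with the signal of an array was not tested, so the 6 do not exclude a dye or probe effect. For the other 18, among them RARRES2 and MTAP, a constant probe effect and a lasting change from 4 h on cannot be told apart, because no array had the dyes exchanged. RAB13, also among the 18, was saturated in the treated channel on all 8 arrays, which limits the difference between times that its ratio can show.

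Calls were also made among spots without an identity on the array, which no comparison used. Of 51 such spots, 27 were bright enough to test and 5 were called averaged over times, all of them higher after PGJ2. Of all probes 12.4% were called, and no test set these spots apart from other probes. What they measure is not known.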

How the results depend on the processing

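Leaving out the 2 dimmest arrays (8 h replicate 1 and 24 h replicate 2), the filter against empty positions and the term for arrays with signal at empty positions were chosen after seeing the data; the other alternatives were chosen before the data were examined.

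Among comparisons of probes with calls, the average over times had the steadiest count. Its count of 1975 probes stayed within 1.5 times under the processing alternatives except a minimum 2-fold change (348), the deposited ratios (1216, fewer probes tested) and the 2 dimmest arrays left out (1115). With 1 array left out it was 1031 to 1982. Of the 1975 probes, between 1972 and 1975 kept their sign in the alternatives of background, normalization and model that tested them all. In the deposited ratios 1606 of 1614 did. These probes were called on the same spots, so a kept sign says little. Fewer kept their call in those alternatives, a minimum 2-fold change aside: from 1367 with print-tip loess to 1940 with eBayes trend and robust. In the deposited ratios 880 of 1614 kept it. The 115 called named genes gave 2819 comparisons with alternatives, of which 2544 kept direction and call, 274 lost the call and 1 turned: UBE2H, from 0.54 to -0.0145 without background correction. The 25 uncalled ones gave 571 of 594 the same and 23 that gained a call.

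Counts at single times depended on the processing. The main counts were 15 at 4 h, 44 at 8 h, 27 at 16 h and 537 at 24 h. An offset of 10 gave 7, 15, 16 and 266. Without background correction they were 7 at 4 h, 13 at 16 h and 1045 at 24 h, and with spot medians 7 at 4 h. Print-tip loess gave 24 at 8 h and 201 at 24 h, and median centring 29 at 4 h and 97 at 8 h. Scaling between arrays gave 24, 187, 71 and 36. The filter on all 8 arrays, with fewer probes tested, gave 29, 155 and 58 at 4, 8 and 16 h. Array weights gave 126, 48 and 108 at 8, 16 and 24 h. The 2 arrays of a time had equal weights, so this alternative weighted times and could not set a poor array apart from its pair. Each time fitted alone gave 588, 4 and 154 at 8, 16 and 24 h. The deposited ratios gave 5 at 4 h. The 2 dimmest arrays left out gave 4, 0 (limma), 10 and 78; for 8 h the unadjusted count with all arrays was 1616. The filter against empty positions gave 24 and 71 at 4 and 8 h, and the term for such arrays 1 at 4 h and 93 at 24 h. Except where fewer arrays or probes were used, the cause was not tested.

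With 1 array left out the counts were 3 to 95 at 4 h, 1 to 83 at 8 h, 1 to 64 at 16 h and 50 to 491 at 24 h, where a lone array is assumed to vary like the others. Late minus early and any difference between times stayed at 0 by limma under all alternatives that were run.

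The 13 lists called on average and 8 called late minus early both became 0 with an estimated correlation on the probes measured on all arrays. On those probes the averaged autophagy (camera, adjusted p = 0.0515) and matrix calls (0.0670) and the late neurodegeneration call (0.0617) were lost with the preset correlation as well. So were those of immediate early (0.185) and tubulin genes (0.0851) at 8 h, autophagy at 16 h (0.143) and apoptosis at 24 h (0.199). Their loss is not shown to come from the correlation. For the other lists the estimate also came with fewer degrees of freedom (4 residual ones). Whether these or the correlation took away the calls was not tested, and no list passed with the estimate at any single time either. The counts with the preset correlation were 13 averaged and 8 late. With 1 array left out they were 10 to 14 and 4 to 12. The 8 late lists gave 93 of 128 comparisons the same and 35 without the call, and the 13 averaged ones 185 of 208 and 23.

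With the replicate number as a block the counts were 17 at 16 h and 1882 averaged, and 6 lists were called late minus early, without the ubiquitin and neurodegeneration lists (adjusted p = 0.0645 for each). The deviations of arrays with the same number correlated across probes with r from -0.25 to 0.20, which neither shows a pairing nor excludes one. Both the highest r of any 2 arrays (0.56, 16 and 24 h replicate 1) and the lowest (0.20, 4 and 24 h replicate 1) joined arrays of the same number.

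Signal over background limits what the dimmer arrays show: in the treated channel 28.3% of the probes were above background on 8 h replicate 1 and 39.7% on 24 h replicate 2.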

Other observations

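The test of a later onset was chosen only after the result was seen.

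Several of the largest ratios averaged over times belonged to probes that could not be given a current gene name, chosen here after their values were seen. A 90-kDa heat-shock protein mRNA rose by log2 2.43 (SE 0.17, n = 8) and a partial HSP90 mRNA by 2.25 (SE 0.21, n = 8), both cytosolic chaperones. A probe for 5.8S ribosomal RNA, which is not a messenger RNA, rose by 3.32 (SE 0.32, n = 8), and whether RNA quality or labelling differed between the channels was not tested. A probe for the HSPC285 partial mRNA rose by 4.84 (SE 0.21, n = 8). Probes for a partial synaptotagmin 7 mRNA, a calcium sensor of vesicle fusion, and for a HOXC8 exon, a patterning factor, had ratios of -2.64 (SE 0.24) and -2.04 (SE 0.28).

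Some members of the fixed lists had large ratios outside the rule for named genes and are named after their values were seen. CEBPB, a transcription factor of stress responses, rose by 1.71 (SE 0.36), EGR1, an immediate early factor, by 1.38 (SE 0.27) and PRNP, the prion protein, by 1.34 (SE 0.15). HSP90B1, the HSP90 of the endoplasmic reticulum, rose by 0.94 (SE 0.23).

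The proteasome subunits appeared to change later than the chaperone and ATF4 target genes. The late minus early median was 0.69 for 28 proteasome genes and -0.01 for 48 genes of the HSF1 and ATF4 lists, a difference of 0.71. A permutation test over genes gave a two-sided p of 1e-05, the smallest that 100000 permutations can give; genes are not independent replicates and the proteasome genes were picked for their late rise, so this p does not cover the spread between arrays or that choice. A later onset of the proteasome genes is a candidate explanation, found and tested on the same data.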
